A study of Homo sapiens with 4 samples.

How the data were processed

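Binding of the transcription factor USF1 was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in Huh7 cells, a line derived from a human hepatocellular carcinoma. USF1 was overexpressed, per the series' design text, and per the labels' protocols the crosslinked and sonicated chromatin was precipitated with an anti-FLAG antibody. There were 4 libraries: 2 from immunoprecipitated DNA (IP 1 and IP 2) and 2 from input chromatin (input 1 and input 2). Paired-end libraries were read on a NovaSeq instrument, per the labels' protocols. The labels number the replicates but do not say whether they came from separate cultures. Signal from an IgG library or from cells without the tagged protein was not used here.

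The data analysed were 2 peak lists, 1 per IP, each called against the input of the same number, per the file headers. Peaks were called with MACS 1.4.2 at a p cutoff of 1e-05, with an effective genome size of 2.7e+09, a band width of 300 bp, a model fold range of 10 to 30 and local background windows of 1000 and 10000 bp, per the file headers. Per the file headers, at most 1 tag was kept per position and the larger library of each pair was scaled to the smaller. Bowtie2, deepTools, HOMER and the GRCh38 build are named per the submitters' processing notes, with no role or version given there. Replicates were not pooled, per the file headers. Reads kept after removal of duplicates numbered 47165647 for IP 1, 46345938 for input 1, 43942638 for IP 2 and 43562726 for input 2, per the file headers.

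For each peak the authors deposited a count of IP tags, which is not scaled to library size. The authors' fold enrichment is the ratio of IP tags at the summit to the tags that the caller expected there from input and local background. The deposited score is minus 10 times log10 of the caller's Poisson p. The deposited false discovery rate (FDR) is a percent, obtained by the caller from peaks found with IP and input swapped, and the deposited values reach a ceiling of 100%. All scores, folds, tag counts and FDRs of single peaks are the authors' own. They were used here to describe, rank and filter peaks, and no test was made between the 2 lists.

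The analyses below were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9. A peak was shared when it overlapped a peak of the other list by at least 1 bp. The number of shared peaks was set against 1000 random placements of the list 2 peaks on their own chromosomes with their widths kept (permutation test, one-sided). Tag counts and folds of shared peaks were compared with Spearman's rho and with Pearson's r of log2 values, which are across peaks. Peaks are not independent replicates, so no p is given for these. Intervals for shares are Wilson intervals at 95% and cover counting error only.

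Gene positions came from a RefSeq gene table of GRCh38.p14, the build the peaks use, with 20037 protein-coding genes. The table used here gives a start and an end for each gene without its strand. Distances planned to transcription start sites were therefore taken to the nearer end of a gene, which can be its 5' or its 3' end, and a gene-end peak is one whose centre lies within 1000 bp of an end. The share of shared peaks at gene ends was compared with 10 random positions per peak on the same chromosome (two-sided Fisher's exact test). Exon and intron positions are not given. Genome sequence was not used here, so the planned tests of the USF1 recognition sequence (the E-box) and of its flanking bases were not run.

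In each of 22 gene lists, 12 written by hand and 10 defined by symbol patterns, members were compared with all other protein-coding genes for having a shared gene-end peak. Two-sided Fisher's exact tests were used, with Benjamini-Hochberg adjustment over the 22 lists. Every hand-written symbol matched a gene, and an older and a newer symbol of the same gene were counted once. The lysosome and autophagy list was drawn from the known CLEAR network (coordinated lysosomal expression and regulation). It shares 7 genes with the vacuolar ATPase list. The lists of lipid and glucose metabolism and of bHLH-ZIP factors share 3 genes, and the clock list shares 2 with the other transcription factor families.

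Groups, tests, gene lists and the rule for naming genes were fixed before the data were examined. The rule takes USF1, USF2 and MYC whatever their values. It then takes the 10 shared gene-end peaks with the highest fold (the lower of the 2 lists' values) and the 5 highest shared peaks over 10000 bp from any protein-coding gene end. It also takes up to 4 members of each list, and the 3 unshared gene-end peaks of highest fold in each peak list. Alternatives tried were stricter thresholds (fold of at least 8, p of at most 1e-10, FDR of at most 5%), other overlap rules and placements, other gene-end distances and backgrounds, peak summits in place of centres, and each list alone. Peaks on contigs other than chromosomes 1 to 22, X and Y (7 in list 1 and 12 in list 2) were left out of the comparisons with gene positions. No list of regions prone to artefacts was applied. Some genes that the rule takes are not reported here.

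The overlap count and the list test were tested on simulated data. With overlaps planted among the 14300 peaks of list 1, 100% were recovered, and 1.91% of the other peaks overlapped by chance. The planted peaks were slightly shifted copies that had to overlap, so their recovery checks the counting alone. Of simulated lists of 50 genes with 40% against 10% carrying a peak, 100% had a p under 0.05, as did 3.9% of random lists. Simulated genes carried peaks independently, whereas neighbouring genes in the data can share a peak.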

Results

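USF1 occupancy in Huh7 hepatocellular carcinoma cells was recorded as 2 peak lists, list 1 (IP 1 against input 1) and list 2 (IP 2 against input 2), to find the genes that overexpressed USF1 binds. USF1 is a bHLH-ZIP transcription factor that recognises E-box sequences. The 4 libraries kept between 43562726 (input 2) and 47165647 (IP 1) tags after removal of duplicates. With 2 lists, the spread between replicates is given as both values, and the counting intervals leave out any variation between cultures.

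The strongest gene-end peaks found in both lists lay at GET4, CLCN7, LAMP1, BAX and the neighbouring ends of AMDHD2 and ATP6V0C. GET4, which acts in the insertion of tail-anchored membrane proteins, carried a peak of 43.82-fold over input in list 1 and 41.04-fold in list 2. The peak at CLCN7, a lysosomal chloride-proton exchanger, reached 34.25-fold and 52.26-fold, and that at LAMP1, a lysosomal membrane glycoprotein, 60.28-fold and 32.83-fold. The 2 lists held 14300 and 27325 peaks, and 5336 of the list 1 peaks overlapped a list 2 peak (37.3%, 95% Wilson interval 36.5 to 38.1%). In list 2, 5346 peaks overlapped a list 1 peak (19.6%, 19.1 to 20.04%). Random placement gave a mean of 287.8 overlaps and a highest count of 342, so the observed number was 18.5 times the chance mean (one-sided permutation p = 0.000999, the smallest that 1000 placements can give). With gene-end peaks placed at gene ends and the others elsewhere, the chance mean was 566.7 and the ratio 9.42.

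Median fold over input was 5.83 in list 1 and 5.6 in list 2, and the highest values were 60.28 and 65.37. The lists differed in how they stood against their swapped controls. In list 1, 274 peaks (1.92%) had an FDR of 5% or less and 9202 (64.3%) were at 100%. In list 2, 8412 peaks (30.8%) had an FDR of 5% or less and the highest FDR was 25.85%. Of the 274 list 1 peaks, 258 (94.2%) overlapped a list 2 peak, against 26.9% of those at an FDR of 100%. By score, the shared part was 76.4% in the highest 10% of list 1 and 19.9% in the lowest 10%, and 64.8% and 6.37% in list 2.

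**Figure D1:**
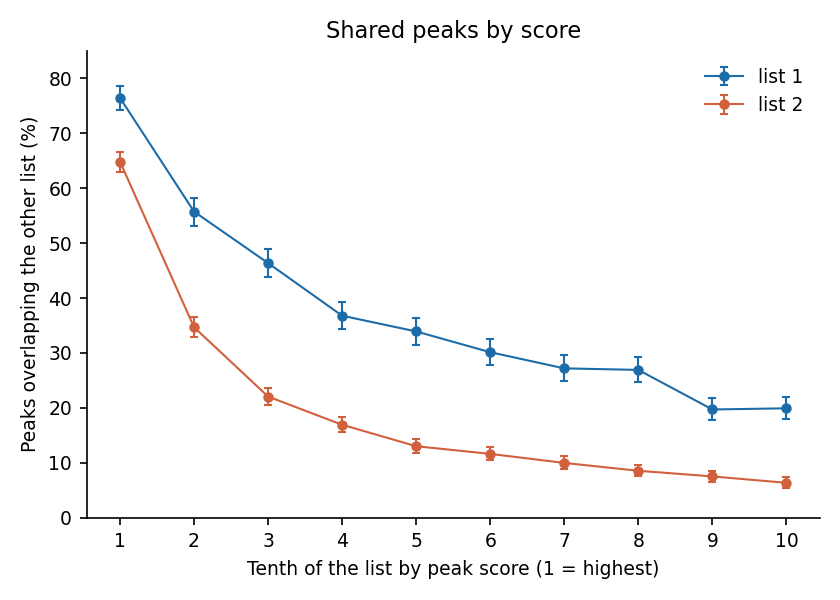
Percent of peaks that overlap a peak of the other list (vertical axis) by rank in each list's own score (horizontal axis, 10 equal bins, 1 is the highest), with 95% Wilson intervals as bars. The share was 76.4% in the highest bin of list 1 and 64.8% in that of list 2, and 19.9% and 6.37% in the lowest bins.

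At the 5336 shared peaks, tag counts of the 2 lists ranked alike, with a Spearman's rho across peaks of 0.809 (0.800 to 0.818) and a Pearson's r of log2 counts of 0.825. Folds over input, which also depend on the input libraries, ranked less alike (rho 0.569, Pearson's r 0.627). The median fold was 6.37 in list 1 and 7.05 in list 2, and 3361 shared peaks (63.0%) had the higher fold in list 2. LAMP1 went the other way, and GET4 and BAX had values within 3 units of each other. Summits of shared peaks lay a median of 38 bp apart, and 4036 (75.6%) lay within 100 bp.

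**Figure D2:**
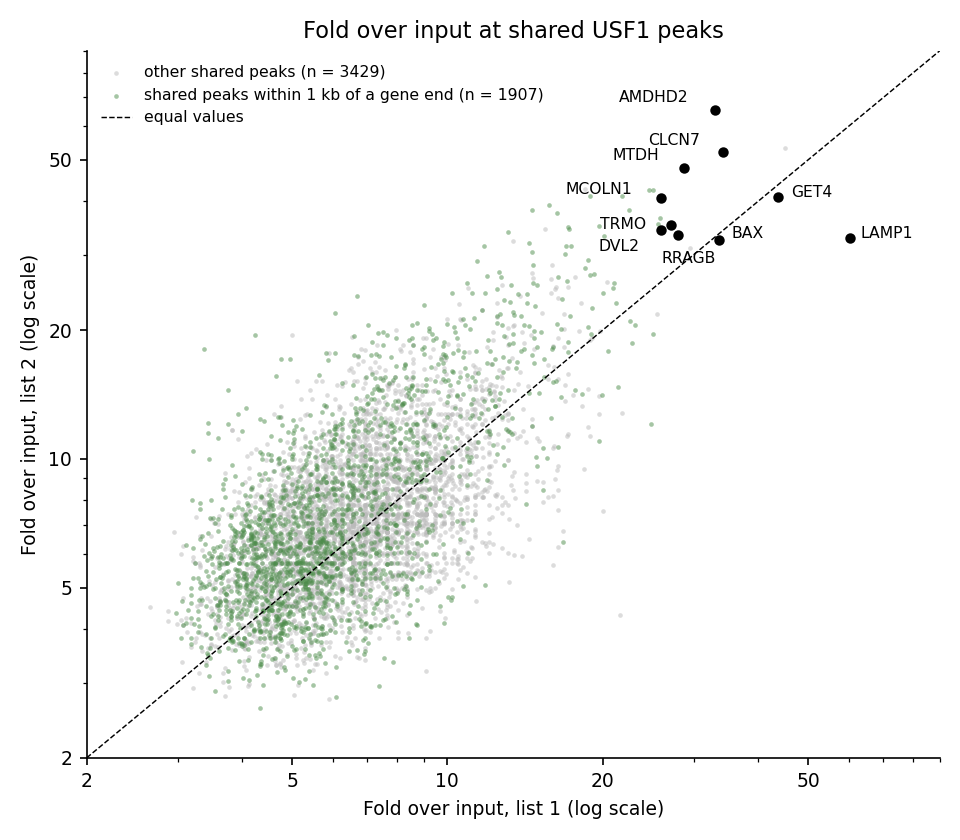
Fold over input of each shared peak in list 1 (horizontal, log scale) and list 2 (vertical, log scale), with 1907 gene-end peaks in green, 3429 others in grey and the 10 named gene-end peaks in black (AMDHD2 marks the peak shared with ATP6V0C). GET4 and BAX lie near the line of equal values, LAMP1 below it (60.28 and 32.83) and CLCN7 above it (34.25 and 52.26).

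Shared peaks were concentrated at the ends of protein-coding genes. On the assembled chromosomes, 1907 of 5335 (35.7%, 34.5 to 37.0%) had their centre within 1 kb of one, against 2.85% of 53350 random positions (odds ratio 18.9, 95% interval 17.6 to 20.5, two-sided Fisher's exact p below 1e-300). The p counts each peak as independent and does not measure variation between replicates. Against random positions within 500 kb of each peak, 3.96% of which lay at gene ends, the odds ratio was 13.5, an alternative chosen after the data were seen. Over all peaks of a single list, the share was 19.2% in list 2 (odds ratio 8.74) and 17.6% in list 1 (odds ratio 8.34), and for shared peaks the odds ratio was 5.51 within 5 kb and 9.74 with all annotated genes. The shared gene-end peaks lay a median of 145 bp from the gene end, at 2306 of 20037 genes. A further 1385 shared peaks lay inside protein-coding genes and 2043 between them, a class that can include non-coding genes. Peaks found in list 1 alone were at gene ends in 6.81% of cases and those in list 2 alone in 15.2%. Among peaks with an FDR of at most 5% in both lists, the share was 69.96% (177 of 253; exact p = 9.146e-159), an alternative chosen after the data were seen.

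The 10 strongest shared gene-end peaks also included MTDH, RRAGB, TRMO, MCOLN1 and the facing ends of DVL2 and PHF23. The GET4 peak spanned positions 875894 to 877112 of chromosome 7 in list 1, with its centre 51 bp outside the gene. CLCN7 had its peak at 1474523 to 1475668 of chromosome 16, 67 bp from the gene's end. Also on chromosome 16, the peak at 2519879 to 2520892 had its centre 14 bp inside AMDHD2 and within 1 kb of the end of ATP6V0C, a membrane subunit of the vacuolar proton pump. Its folds were 32.99 and 65.37. LAMP1 had its peak at 113296445 to 113297634 of chromosome 13. The peak at BAX, a pro-apoptotic BCL2 family member, was at 48954372 to 48955630 of chromosome 19 (33.56-fold and 32.5-fold), and that at MCOLN1, a lysosomal cation channel, at 7522137 to 7523159 of the same chromosome (25.96-fold and 40.65-fold).

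MTDH, which encodes metadherin, had a peak of 28.69-fold and 47.81-fold at 97643589 to 97644563 of chromosome 8. RRAGB, a Rag GTPase that signals amino acid supply at the lysosome, had 28.04-fold and 33.29-fold at 55717393 to 55718276 of chromosome X. TRMO, a tRNA methyltransferase, had 27.16-fold and 35.24-fold at 97921782 to 97922797 of chromosome 9. The peak between DVL2, a Wnt pathway protein, and PHF23 had 25.89-fold and 34.29-fold at 7234003 to 7235109 of chromosome 17. All 10 peaks had an FDR of 0 in both lists. Ranked by tag count instead, GET4 and LAMP1 were the 2 of these 10 peaks that stayed among the first 10.

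Shared peaks over 10 kb from any protein-coding gene end numbered 2797 (52.4%). The strongest lay inside FNDC3A, at 49110023 to 49110664 of chromosome 13, with 29.49-fold and 31.17-fold. Next came a peak inside SLC36A1, a lysosomal amino acid transporter, at 151447062 to 151448065 of chromosome 5 (25.49-fold and 21.8-fold). The other 3 lay between protein-coding genes. One was 70161 bp from KCTD3 on chromosome 1 (19.08-fold and 19.22-fold), another on chromosome 14 was 111 bp from the long non-coding RNA gene LOC107984696 (18.93-fold in each list), and the last was 28800 bp from MMP20 on chromosome 11 (18.5-fold and 42.85-fold). None of these 5 peaks stayed among the first 5 when ranked by tag count.

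Lysosome and autophagy genes had shared gene-end peaks more often than other protein-coding genes, in 28 of 49 (57.1%) against 11.4% (odds ratio 10.4, 5.67 to 19.2, two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 1.651e-13). CLCN7, LAMP1 and MCOLN1 led the list, followed by HEXA, a subunit of beta-hexosaminidase (25.59-fold and 35.43-fold). Others included the hydrolase genes GLA, GAA, CTSA, CTSB, CTSD and TPP1 and the autophagy genes GABARAP, MAP1LC3B, UVRAG and WIPI1. At a fold of at least 8 in both lists 19 of the 49 had such a peak, and at an FDR of at most 5% in both lists 15 had one (adjusted exact p = 1.818e-18 and 6.26e-17). Of the 24 subunits of the vacuolar ATPase, which acidifies lysosomes, 8 had a shared peak (33.3%, odds ratio 3.85, adjusted exact p = 0.0129), with ATP6V1H at 22.5-fold and 38.25-fold and ATP6V0D1 at 16.67-fold and 23.59-fold. Without the 7 subunits that the lysosome list also holds, 4 of 17 remained (odds ratio 2.37, two-sided Fisher's exact p = 0.123), and with each peak counted for its nearest gene alone the odds ratio was 3.2 (adjusted exact p = 0.0525). At a fold of at least 8 in both lists, 6 of the 24 had one (odds ratio 15.8, adjusted exact p = 8.561e-05), with the 7 overlapping subunits kept in.

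**Figure D3:**
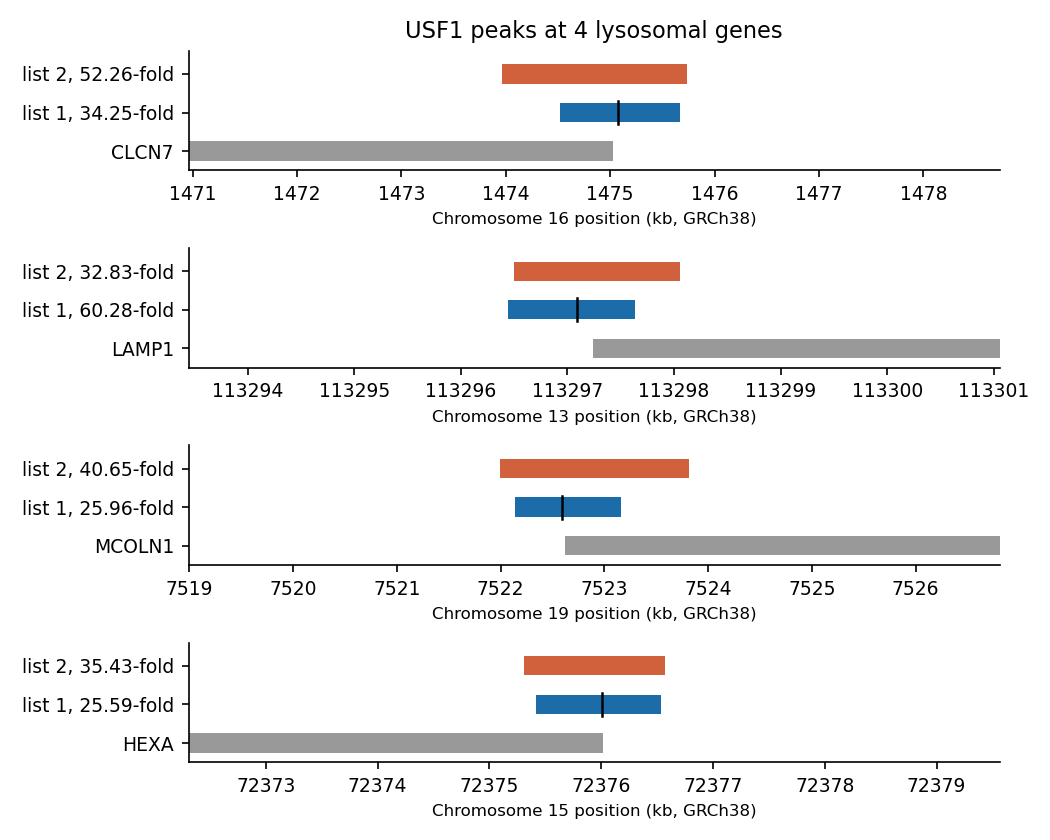
Positions (horizontal axes, kb on GRCh38) of the list 1 peak (blue, black line at its summit), the list 2 peak (orange) and the gene (grey, running on beyond the window) at CLCN7, LAMP1, MCOLN1 and HEXA. The list 1 peak covers a gene end in each, with centres 24 to 200 bp from it.

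Unfolded protein response genes had shared peaks in 11 of 25 (44%, odds ratio 6.07, adjusted exact p = 0.00024). By the lower of the 2 folds, the ER quality control gene SEL1L (6.19-fold and 6.72-fold) and the chaperone gene DNAJB9 (5.64-fold and 15.71-fold) led. The chaperone gene HSP90B1 (6.09-fold and 5.54-fold) and DNAJB11 (5.4-fold and 6.38-fold) followed. The median lower fold of all shared gene-end peaks was 5.25. FDRs in list 1 were 100% for SEL1L and DNAJB11, 92.93% for DNAJB9 and 68.54% for HSP90B1, against at most 10.02% in list 2. Clock genes had shared peaks in 8 of 19 (42.1%, odds ratio 5.61, adjusted exact p = 0.00313). These included the REV-ERB genes NR1D2 (8.15-fold and 13.34-fold) and NR1D1 (11.82-fold and 5.08-fold), as well as DBP (6.25-fold and 9.47-fold) and PER3 (6.25-fold and 10.98-fold). List 1 FDRs were 2.08% for NR1D2, 7.45% for NR1D1 and 100% for DBP and PER3, against at most 5.22% in list 2. With a fold of at least 8 required in both lists, 0 of the 25 unfolded protein response genes (adjusted exact p = 1) and 1 of the 19 clock genes (odds ratio 2.61, adjusted exact p = 0.839) had one.

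Nucleolar and growth genes had shared peaks in 11 of 37 (29.7%, odds ratio 3.26, adjusted exact p = 0.00831). The G1 kinase gene CDK4 (18.45-fold and 27.92-fold) and the translation initiation factor EIF4E (12.5-fold and 21.6-fold) led. UTP20 (8.04-fold and 13.68-fold, list 1 FDR 48.44%) and SRM (6.82-fold and 7.44-fold, list 1 FDR 100%) followed. At a fold of at least 8, 3 of the 37 had one (odds ratio 4.16, adjusted exact p = 0.183), and counting nearest genes alone gave an odds ratio of 2.65 and an adjusted exact p of 0.0525.

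Because the study asks which transcription factors USF1 regulates, factor genes were compared by family. bZIP genes had shared peaks in 11 of 41 (26.8%, odds ratio 2.83, adjusted exact p = 0.015), with JUND at 7.54-fold and 10.79-fold, ATF1 at 7.52-fold and 9.97-fold, BATF3 at 7.48-fold and 9.2-fold, and ATF4, a stress response activator, at 7.25-fold and 12.94-fold. Their FDRs in list 1 were 4.51% (JUND), 100% (ATF1), 38.88% (BATF3) and 25.75% (ATF4), against at most 0.31% in list 2. In this family the call was lost within 500 bp of a gene end (odds ratio 1.83, adjusted exact p = 0.273), and 0 of the 41 had a peak of at least 8-fold in both lists. bHLH-ZIP genes, the family of USF1 itself, had them in 6 of 23 (26.1%, odds ratio 2.72, adjusted exact p = 0.0857). MAX, the partner of MYC, had 16.25-fold and 15.24-fold, MLX 13.36-fold and 12.47-fold, MGA 10.42-fold and 14.04-fold, and SREBF2, a regulator of sterol synthesis, 6.25-fold and 12.1-fold. For this family the adjusted exact p was 0.00438 without replicate 1, 0.0321 within 5 kb and 0.0144 at an FDR of at most 5% in both lists, where MAX, MLX and MGA remained. It was 0.207 without replicate 2 (odds ratio 2.01), 0.169 within 500 bp and 0.0644 at a fold of at least 8.

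C2H2 zinc finger genes had shared peaks in 46 of 509 (9.04%, odds ratio 0.759, adjusted exact p = 0.124, 0.0406 within 5 kb, 0.0112 without replicate 1 and 0.9 without replicate 2, where the odds ratio was 1.015), led by ZNF507 (21.39-fold and 14.75-fold) and ZNF292 (14.58-fold and 30.39-fold). Other transcription factor families had them in 30 of 316 (9.49%, odds ratio 0.804, adjusted exact p = 0.371). The strongest of these included the homeobox genes HOXC13 (19.24-fold and 27.05-fold), HOXB7 (17.09-fold and 26-fold) and HOXA7 (16.41-fold and 26.69-fold). None of USF1, USF2 and MYC had a peak inside the gene or within 1 kb of its ends in either list. The nearest peak centre to USF1 was 72064 bp away in list 1 and 51396 bp in list 2.

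Cell cycle and tumour genes had shared peaks in 8 of 33 (24.2%, adjusted exact p = 0.0879). Among them were BRCA2 (10.12-fold and 7.68-fold, list 1 FDR 22.45%) and CDKN2B (8.35-fold and 7.44-fold, list 1 FDR 59.34%). The adjusted exact p was 0.0461 without replicate 2, 0.00626 without replicate 1 and 0.0257 within 5 kb of a gene end. It was 0.221 within 500 bp and 0.209 with nearest genes, and 0 of the 33 had a shared peak at a fold of at least 8 or an FDR of at most 5% (adjusted exact p = 1). Lipid and glucose metabolism genes had them in 8 of 47 (17.0%, adjusted exact p = 0.341, and 0.0456 without replicate 1), with SCD, a fatty acid desaturase, at 12.02-fold and 14.52-fold and INSIG1, a brake on sterol synthesis, at 12.97-fold and 11.77-fold. The SCD peak lay 273 bp from the gene's end coordinate and the INSIG1 peak 222 bp from its start coordinate. Without strand, these cannot be told to be 5' or 3' ends, so promoter binding at SCD is not shown. Oxidative phosphorylation genes had shared peaks in 16 of 85 (18.8%, adjusted exact p = 0.0857, 0.00332 without replicate 1, 0.00679 within 5 kb and 0.111 without replicate 2), with SDHA at 7.21-fold (list 1 FDR 46.46%) and 13.77-fold. At a fold of at least 8, 1 of the 85 had one (odds ratio 0.558). The counts were 12 of 87 for cytosolic ribosomal proteins (adjusted exact p = 0.578, and 0.0067 without replicate 1), 11 of 77 for mitochondrial ones (0.576, and 0.0113 without replicate 1), 9 of 73 for histones (0.894, and 0.00045 without replicate 2 with an odds ratio of 2.8, but 0.389 without replicate 1 with an odds ratio of 0.761) and 5 of 44 for proteasome subunits (1).

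Olfactory receptors and keratins carried shared peaks less often than other genes. Olfactory receptors had one in 3 of 392 (0.765%, odds ratio 0.0581, adjusted exact p = 7.72e-16) and keratins with keratin-associated proteins in 2 of 149 (1.34%, odds ratio 0.104, adjusted exact p = 2.895e-05). With an FDR of at most 5% in both lists, 0 of either had one (adjusted exact p = 0.134 and 0.834), and the keratin call was also lost at a fold of at least 8 (0.292). There was 1 among 20 immune cell markers (CD68, itself a lysosomal protein; adjusted exact p = 0.793), 0 among 26 neuronal and erythroid genes (0.111, and 0.00395 without replicate 1 and 0.0461 without replicate 2) and 0 among 19 fibroblast and endothelial markers (0.23, and 0.00392 without replicate 1). Hepatocyte factors and products also had 0 of 30 (95% Wilson interval 0 to 11.4%, adjusted exact p = 0.0857). In list 2 alone, 1 of these 30 genes had a gene-end peak (adjusted exact p = 0.00172) and in list 1 alone 0 had one (0.0418), as with shared peaks within 5 kb (0.0321).

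**Figure D4:**
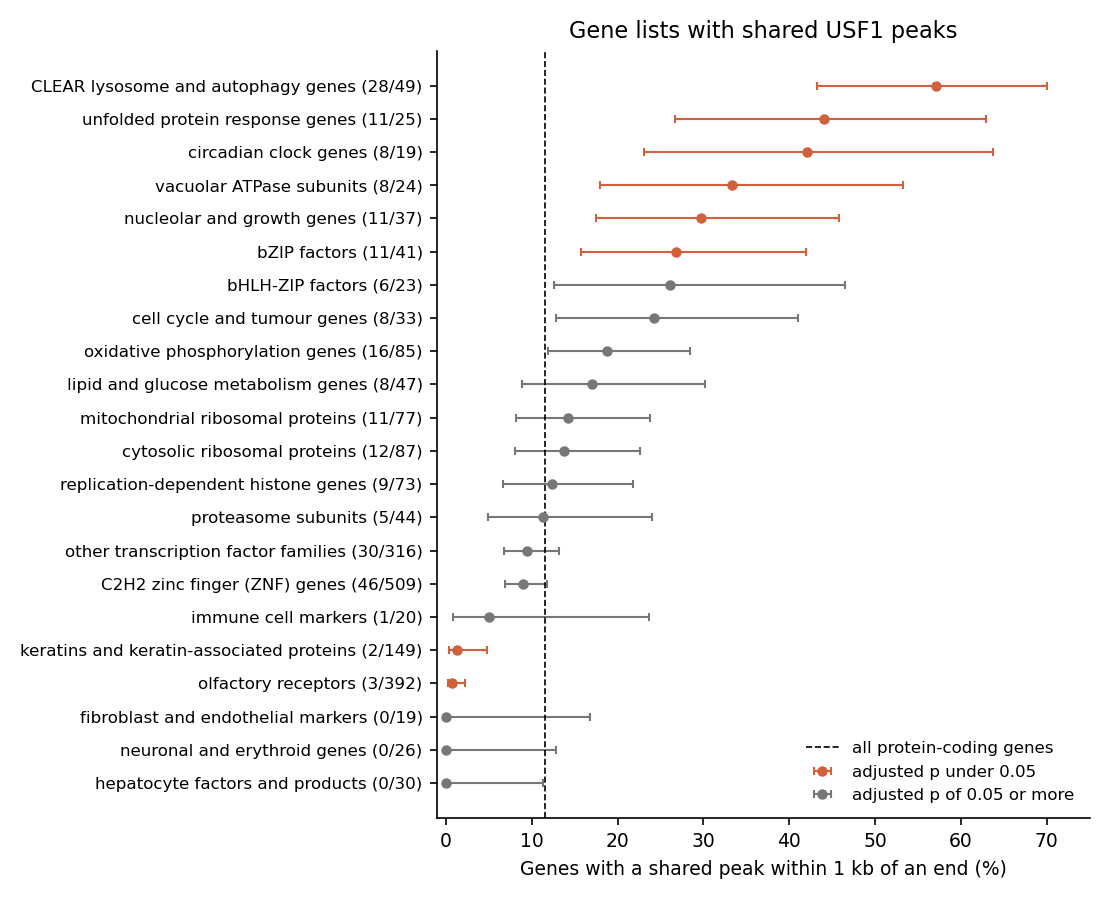
Percent of each list's genes with a shared peak within 1 kb of an end (horizontal axis), with 95% Wilson intervals as bars and members with a peak over members in brackets; the dashed line is the level of all protein-coding genes. The lysosome and autophagy list stands highest at 57.1%, and olfactory receptors (0.765%) and keratins (1.34%) lie below the line.

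Some gene-end peaks were present in a single list. The strongest unshared ones in list 1 were at ZNF804B (11.29-fold), between SEL1L2 and MACROD2 (10.56-fold) and at EIPR1 (10.42-fold), with FDRs of 35.75% to 41.73%. In list 2 they were at RELB, an NF-kB subunit (26.11-fold), ATP6V1C1, a further vacuolar ATPase subunit (21.6-fold), and C14orf132 (17.14-fold), with FDRs of 0 to 0.22%. List 1 peaks were also dense on chromosome 5 from 10 to 50 Mb, which held 1366 of them and 425 of list 2, a stretch chosen after the data were seen.

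**Figure D5:**
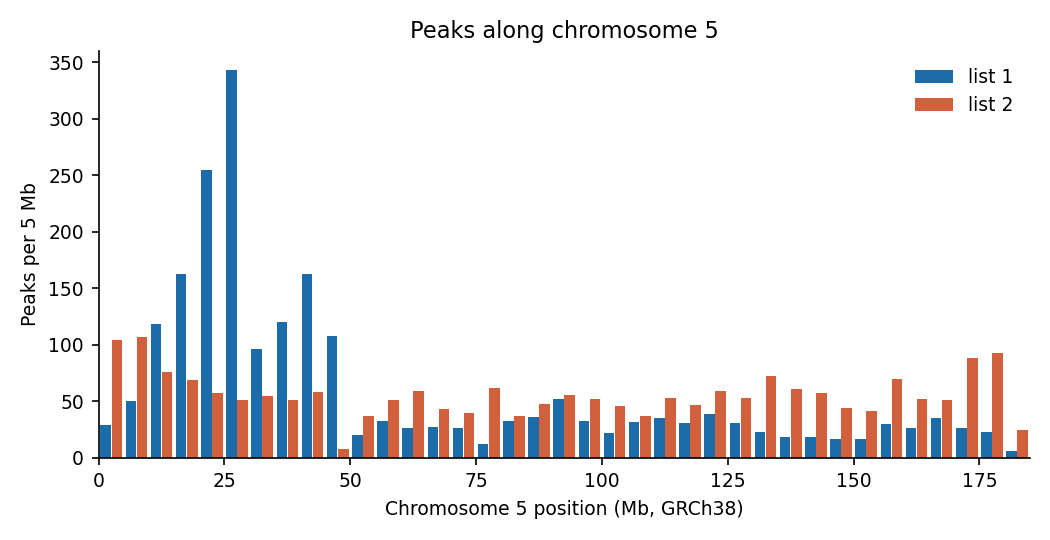
Peaks per 5 Mb (vertical axis) along chromosome 5 (horizontal axis, Mb on GRCh38) in list 1 (blue) and list 2 (orange). From 10 to 50 Mb list 1 had 1366 peaks and list 2 had 425, with up to 343 list 1 peaks in 1 window.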

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

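The FDR thresholds, the 500 bp distance, nearest-gene counting, summits, placement and random positions within 500 kb, the background without olfactory receptors, keratins and ZNF genes, the leaving out of chromosome 5 and the removal of overlapping subunits were chosen after the data were seen. No paired analysis was possible because each list already sets an IP against the input of its own number and gives no count of input tags per peak. Tests needing genome sequence were not run: E-box enrichment, E-box flanks, GC-matched windows, and backgrounds of CpG-rich promoters or of genes with CACGTG. Requiring a fold of at least 8 left 2226 peaks in list 1, 3685 in list 2 and 969 shared; a p of at most 1e-10 left 3162, 6715 and 1493; an FDR of at most 5% left 274, 8412 and 254. Centres at most 100 bp apart gave 2806 shared peaks. The rank correlation between the lists was 0.569 for folds and 0.739 for tags away from gene ends. Overlap stayed above chance in each placement run, with 566.7 chance overlaps when gene-end peaks were placed at gene ends (ratio 9.42) and 368.6 within 500 kb of each peak. Lists with more shared peaks than other genes numbered 6. They numbered 2 at a fold of at least 8 (lysosome and autophagy, and vacuolar ATPase), 3 at the FDR threshold (the same pair and bHLH-ZIP factors), 9 within 5 kb (gaining bHLH-ZIP, cell cycle and oxidative phosphorylation genes), 4 with nearest genes, and 8 to 12 when a replicate was left out. The lysosome and vacuolar ATPase lists share 7 genes, which were removed at the main setting alone, so these 2 calls are not independent. Across 196 list values under other settings, 141 kept their direction and side of the threshold, 15 lost the call, 20 gained one and 23 turned direction, 3 of these among the lost calls and none past the test in the other direction. At a fold of at least 8 the odds ratio turned to 0 for bZIP, unfolded protein response, cell cycle and histone genes, to 0.558 for oxidative phosphorylation genes and to 1.22 for other transcription factor families. At the FDR threshold it turned to 0 for unfolded protein response, cell cycle, histone, oxidative phosphorylation, cytosolic ribosomal and mitochondrial ribosomal genes and to 1.76 for other transcription factor families. These thresholds left fewer genes with a peak; beyond that the cause was not tested. The odds ratio of proteasome subunits turned to 1.24 within 5 kb, 1.14 within 500 bp, 1.23 with nearest genes and 1.2 to 1.27 when a replicate was left out. That of histones turned to 0.793 within 500 bp, 0.857 with nearest genes and 0.761 without replicate 1 (2.8 without replicate 2). It turned to 1.005 for other transcription factor families with nearest genes, and to 1.015 for C2H2 zinc finger genes without replicate 2 (0.76 without replicate 1). Ranking by tag count kept 2 of the 10 named gene-end peaks and 0 of the 5 distal ones. Depth was similar in all libraries, and 2 lists limit every comparison between replicates.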

Other observations

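Tests of sequencing depth, of peak strength at lysosomal genes, of neighbouring gene ends, of gene number on chromosome 5 and of HOX genes were chosen only after the results were seen. Some shared gene-end peaks lay between 2 genes, as at DVL2 and PHF23 or at the peak shared by NDUFA7 and RPS28 (9.94-fold and 11.88-fold). Gene ends within 1 kb of another gene's end had a shared peak in 827 of 6684 cases (12.4%), against 1516 of 33390 lone ends (4.54%; odds ratio 2.97). The comparison decides nothing, because 1 peak counts for both of 2 close ends and lone ends include 3' ends. Which end carried the peak was examined at the 594 genes with a divergent transcript named after them. Of 112 such genes with a shared peak at 1 end alone, 109 (97.3%, 92.4 to 99.1%) had it at the end facing that transcript, which is consistent with the 5' end.

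HOX genes carried some of the strongest peaks among the other transcription factor families. Of 39 HOX genes, 8 had a shared gene-end peak (20.5%) against 11.5% of other genes. The odds ratio of 1.99 (0.788 to 4.43, two-sided Fisher's exact p = 0.0813) leaves a higher rate open, and HOX genes lie in clusters, so they are not independent. The peak with the most tags in both lists, 1358 and 1581, lay between genes at 74513226 to 74515680 of chromosome 17, 6721 bp from CD300LB, with 45.12-fold and 53.46-fold. It falls outside the naming rule and was chosen after its values were seen.

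Among the 10 strongest shared gene-end peaks, 4 lay at lysosome, autophagy or vacuolar ATPase genes, as did 11 of the strongest 50 and 32 of all 1907. The 4 include the peak at ATP6V0C, whose centre lay nearer to AMDHD2 (14 bp) than to ATP6V0C (167 bp). This peak was at the start coordinate of AMDHD2 and the end coordinate of ATP6V0C. Without strand, it cannot be told whether that is the 5' or the 3' end of ATP6V0C, so promoter binding there is not shown. A general pull-down of active promoters was tested against pooled proteasome, oxidative phosphorylation and ribosomal protein genes. Those had shared peaks in 44 of 293 (15.02%). The odds ratio of 7.48 (3.74 to 15.2, two-sided Fisher's exact p = 1.338e-09) argues against such a pull-down as the whole cause. A smaller part for it cannot be excluded, as no IgG or untagged library was used. In list 2 alone, odds ratios against other genes were 2.075 for oxidative phosphorylation, 1.896 and 1.844 for cytosolic and mitochondrial ribosomal proteins and 1.204 for proteasome subunits. List 1 alone gave 1.643, 1.488, 1.379 and 1.266. Peak strength was compared too, and the median lower fold was 10.21 at the 28 lysosome and autophagy genes and 5.23 at 2278 other genes, a difference of 4.97 (permutation p = 1e-05, the smallest that 100000 resamples can give). The hypothesis that USF1 binds this gene set preferentially stays open, since recognition sequences, native USF1 and the related factors of the CLEAR network were not analysed here.

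The 1262 peaks of list 1 on chromosome 5 from 10 to 50 Mb that list 2 lacked were 10.7 times as dense as such peaks genome-wide, and 0 of them lay at gene ends. Copy number gain as the whole cause would raise both lists of 1 cell line, but list 2 peaks were 1.18 times as dense there as over the genome, against 7.24 times for list 1. The genome average was not matched for gene number, with which list 2 peak counts rose (Spearman's rho 0.488 across 5 Mb windows). Whether a gain is present therefore stays open, and the values show only that the 2 lists differ there. The region held a median of 127.5 peaks only in list 1 per 5 Mb window, against a 95th percentile of 37.25 in 356 other windows with no more genes. That comparison cannot decide on a low number of genes, because the region was picked for its many list 1 peaks. The 356 windows held a median of 9, so few genes did not usually go with so many such peaks. Those at 95 and 25 Mb of chromosome 11 held 148 and 137. Whether the region's 1262 peaks were calls near the threshold stays open. Of them, 0.872% (11 peaks) had an FDR of 5% or less, against 0.065% of unshared list 1 peaks elsewhere. So few list 1 peaks pass anywhere (1.92%) that a low share decides nothing. A gain combined with a difference between IP 1 and input 1, and any biological explanation, were not tested.

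List 2 had 27325 peaks and list 1 had 14300. Deeper sequencing of IP 2 is argued against, since it kept 0.932 times the tags of IP 1. A difference in regional composition between IP and input that runs in opposite ways in the pairs is a candidate explanation. Peaks only in list 2 had a median of 6 protein-coding genes per Mb around them and those only in list 1 had 3, a ratio of 2, and random positions had 4. The median of 3 includes the 1262 peaks of the chromosome 5 stretch. Across 619 windows of 5 Mb, Spearman's rho with gene number was 0.0458 for peaks only in list 1. It was 0.458 for those only in list 2 and 0.533 for shared peaks, so opposite directions were not seen in these counts. In list 1, down to the last score with an FDR under 100%, the deposited FDRs imply 5096 peaks with IP and input swapped, against 5098 peaks. The swapped number was worked back from FDR and rank and was not itself observed. Below that score it is not known. No biological explanation was tested.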
